A study of Mus musculus with 18 samples.

How the data were processed

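Immunoprecipitated DNA and input DNA were sequenced from primary immature mouse neurons, untreated or given 10 mM 2-DG for 6 h. Of 18 samples, 10 immunoprecipitations had a peak list, and the 8 input samples were not used here. Peaks were aligned and called against mm10 with tools that include BWA, Picard and MACS2, per the submitters' processing notes, which also name DiffBind and give no versions. Each list was called on 1 sample, per the peak names in the deposited files, which all carry 1 run name and 1 lane.

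The deposited lists give, for each summit, a position, a fold enrichment over the local background (a ratio), -log10 p and -log10 q values, and a score that equals 10 times -log10 q cut to a whole number. The lowest -log10 q in the authors' lists ran from 1.32 to 1.77 over the 8 compared lists, so the lists end at different q-values. The fold, the -log10 values and the score are the authors' values for single peaks, and were used only to describe, rank or filter peaks within a list. Lists repeat an interval once for each summit in it, 431 to 1807 times per list among the 8 compared lists. A peak here is therefore a distinct interval, placed at its highest summit. Lists give no read counts, so the depth of each sample is unknown and no limit of detection can be set.

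Groups were taken from titles that matched the description and treatment label. In 4 samples, 2 of them with lists, the title and the description name different treatments. They entered no comparison except as an alternative. The antibody label reads none for control samples and names the ATF4 antibody for 2-DG samples, inputs included, while the series design names that antibody for untreated and treated neurons. Which antibody the control immunoprecipitations had is therefore open. The design states 3 independent replicates, whereas each treatment has 5 lists by title. Because nothing ties lists to separate cultures, p-values measure only the spread between these samples, which may be technical. The extraction text in the labels describes RNA, so the chromatin protocol is not given in the sources used here.

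Gene positions came from a RefSeq table of GRCm38.p6, the assembly that mm10 names. It gives gene starts and ends without strand, exons or sequence. The planned promoter window of 2000 bp around the gene start was therefore replaced by windows of 2000 bp around both ends of each of 21883 protein-coding genes. An end peak can thus lie at the start or at the finish of a gene. The planned split into exons and introns and the planned search for ATF4 motifs were not run. All 298 genes of the 16 lists matched the table, 3 of them through an older name.

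Overlap meant at least 1 bp. Regions are the union of the 8 lists. Per-list measures were compared by two-sided exact permutation tests over 70 assignments, and Jaccard indices by a one-sided exact test over the 35 distinct splits. Gene lists were tested against genes bound in at least 3 of 4 lists with Fisher's exact test, with 0.5 added to each cell for the odds ratio. Benjamini-Hochberg adjustment ran over the 16 lists, or over 8 per-list measures. Intervals on shares of regions are exact binomial at 95% and cover counting error only.

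Named genes followed a rule. It took 10 fixed genes (Bdnf, Atf4, Atf3, Ddit3, Trib3, Asns, Chac1, Sesn2, Cebpb, Hspa5), and up to 10 with an end peak in all 4 2-DG lists and no control list, or the reverse, by mean within-list percentile of fold. Where under 5 were found, genes bound in 3 of 4 against none were added. It also took 10 genes bound in all 8 lists and up to 4 members of each list bound in at least 3 of 4 lists of a treatment. The rule, the gene lists, the planned tests and the alternatives other than those named below as added were fixed before the data were examined. The test of where regions lie and the adjustment over 8 per-list measures were not in that plan.

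Alternatives were -log10 q of at least 2 or 5, fold of at least 5, equal numbers of top peaks per list (3461), autosomes only, leaving out each list, and adding both conflicting lists by title or by description. Widths of 500 and 5000 bp, whole genes with 5000 bp on either side, other overlap rules and 500-bp windows were also tried. Alternatives chosen after seeing the data were counting each summit, leaving out a segment of chromosome 2, leaving out regions of all 8 lists, placing regions by their middle, and a replicate block that exchanges treatments only within pairs of consecutive title numbers.

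The code was tested on simulated data before use. In simulated 4-against-4 lists with 200 planted regions, 199 were untouched by a simulated control peak, and all 199 were recovered. The planted gene list of 30 members among 21883 genes was found, and 0 of 15 other lists passed. In 20 simulations without planted regions the highest count was 0. Simulated peaks were placed at random apart from a set shared by all lists. That 0 therefore tests the code and is no null for the real lists, whose other splits gave up to 45. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.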

Results

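Chromatin immunoprecipitation with sequencing was used to map binding of ATF4, a transcription factor of the integrated stress response, in primary immature mouse neurons. The neurons came from embryos and were kept untreated or given 10 mM 2-deoxyglucose (2-DG) for 6 h. 2-DG is a glucose analogue that blocks glycolysis and disturbs protein glycosylation. The comparison addresses which sites carry ATF4 after 2-DG that do not carry it in untreated neurons. Of 18 samples, 10 had a peak list, and 4 control and 4 2-DG lists had labels that gave 1 treatment. The control lists held 3461, 3784, 8202 and 6811 peaks, and the 2-DG lists held 15240, 7369, 6371 and 5856. Read depth behind the lists is unknown, so a missing peak means only that none was called. The antibody label of the control samples reads none, while the series design names the ATF4 antibody for both treatments.

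Known ATF4 targets carried peaks at their gene ends in the 2-DG lists and seldom in the control lists. Of 33 members of the ATF4 target list, 26 ± 1.15 (SD, n = 4) had a peak within 2000 bp of a gene end (an end peak, here called bound) in a 2-DG list, against 3 ± 4.76 (SD, n = 4) in a control list. The 2-DG lists held 27, 27, 25 and 25 of them, and the control lists held 10, 0, 2 and 0. Atf3, Cebpb and Sesn2, which encode stress-response transcription factors and sestrin 2, had such a peak in 4 of 4 2-DG lists and 0 of 4 control lists. The same held for Trib3, a pseudokinase gene, and for Ddit4, an inhibitor of mTORC1 signalling. Chac1, which encodes a glutathione-degrading enzyme, had a peak in 4 of 4 2-DG lists and 2 of 4 control lists. Ddit3, encoding CHOP, and Asns, encoding asparagine synthetase, had one in 4 of 4 2-DG lists and 1 of 4 control lists, and so did Herpud1.

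The difference in ATF4 targets per list gave a two-sided exact permutation p of 0.0286, the smallest that 4 lists against 4 allow. The adjusted p over 16 gene lists was 0.152. For any gene list to pass after adjustment, 10 of the 16 had to reach that smallest p, and 3 did. With the pair of lists with conflicting labels added by description, the difference fell from 23 to 13.8 targets (exact permutation p = 0.0952, adjusted p = 0.508). Added by title, it stayed at 23 and passed (exact permutation p = 0.00794, adjusted p = 0.0423). That pass reflects the lower p that 5 lists against 5 allow, since the difference was no larger. If lists with consecutive title numbers are taken as pairs, a block chosen after the data were seen, the smallest exact p is 0.125, which is the unadjusted value for the ATF4 targets. Among the 396 genes with an end peak in at least 3 of 4 2-DG lists, 26 were ATF4 targets, an odds ratio of 205 over all 21883 protein-coding genes (Fisher's exact test, adjusted p = 1.33e-38). None was among the 104 genes with an end peak in at least 3 control lists. Genes are not independent replicates in that test. The 6 targets without an end peak in any 2-DG list were Rrm2b, Slc1a5, Slc3a2, Slc7a11, Slc7a3 and Slc7a5, named after their values were seen. Of the amino acid transporter genes in the list, Slc7a1, Slc1a4, Slc6a9 and Slc38a2 did have one in at least 3 of 4 2-DG lists.

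Genes of amino acid metabolism and transfer RNA charging showed peaks in the same lists. Of 15 serine, one-carbon and transsulfuration enzymes, 10.5 ± 0.577 (SD, n = 4) had an end peak in a 2-DG list and 1.75 ± 2.22 (SD, n = 4) in a control list (exact permutation p = 0.0286, adjusted p = 0.152). The 2-DG lists held 11, 11, 10 and 10 of them, and control replicates 1 to 4 held 5, 1, 1 and 0. Pck2, the mitochondrial phosphoenolpyruvate carboxykinase gene, and Aldh1l2, a mitochondrial folate enzyme gene, were bound in 4 of 4 2-DG lists and 0 of 4 control lists. Shmt2 and Aldh18a1 were bound in 4 of 4 and 1 of 4. Of 20 cytosolic aminoacyl-tRNA synthetases, 12 ± 1.83 (SD, n = 4) had an end peak in a 2-DG list and 3.5 ± 4.36 (SD, n = 4) in a control list, which did not pass the test (exact permutation p = 0.0571, adjusted p = 0.229). Control replicate 1 held 10 of the 20 and the other control lists held 2, 1 and 1. Cars, Mars1, Nars and Yars had a peak in 4 of 4 2-DG lists and 1 of 4 control lists. Both groups were enriched among the genes bound in at least 3 2-DG lists, with 10 enzymes (odds ratio 106) and 11 synthetases (odds ratio 67.4), each with a Fisher's exact adjusted p of 4.97e-14.

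Chaperones and degradation factors of the endoplasmic reticulum had few members bound. Of 22, the 2-DG lists held 6, 3, 2 and 2 and the control lists held 0 (exact permutation p = 0.0286, adjusted p = 0.152). Atf6, a sensor of unfolded protein, had an end peak in 4 of 4 2-DG lists, and Hspa5, encoding the chaperone BiP, in 3 of 4, with 0 of 4 control lists for either. Enrichment of this group among recurrently bound genes did not pass (2 members, Fisher's exact adjusted p = 0.238).

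**Figure D1:**
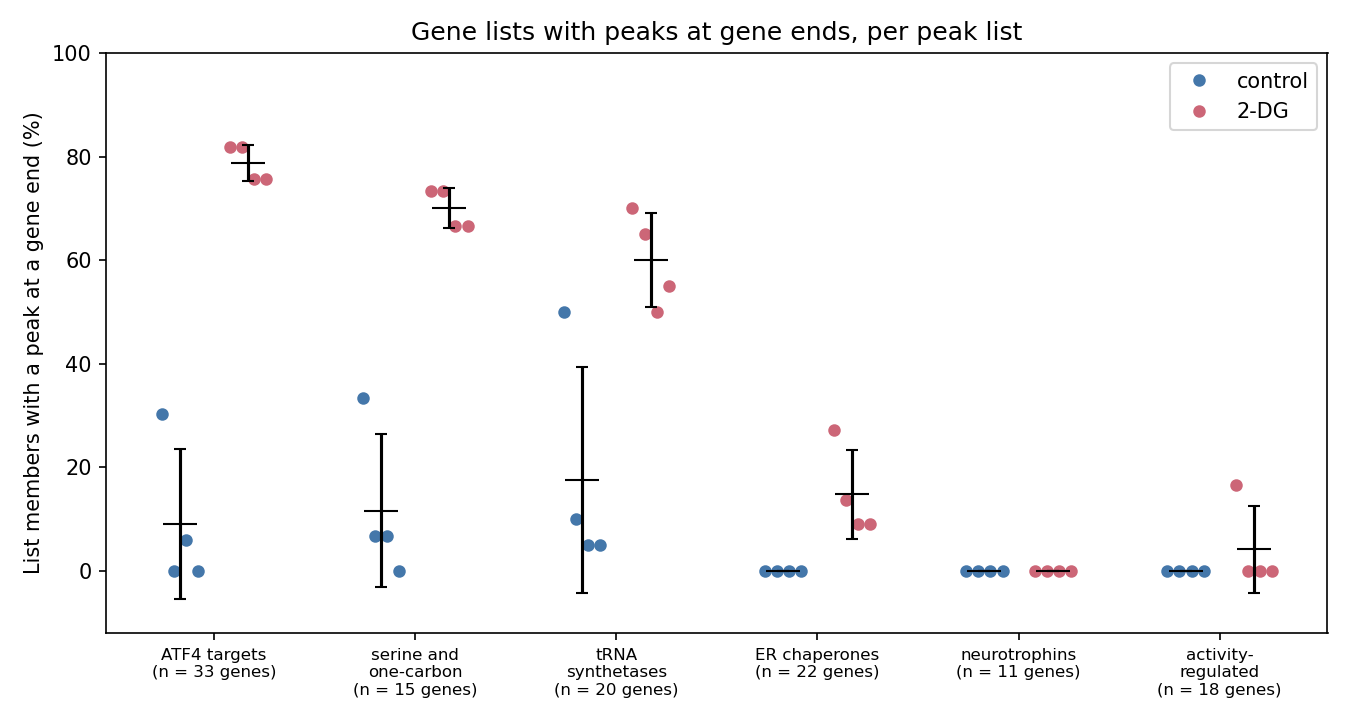
Percent of the members of 6 gene lists with a peak within 2000 bp of a gene end, with 1 point per peak list, a bar at the mean and an error bar of 1 SD (n = 4 per treatment). The 2-DG lists held 25 to 27 of the 33 ATF4 targets, while neurotrophins were at 0 in all 8 lists.

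Neurotrophin and receptor genes had no end peak in any of the 8 lists, and Atf4 itself had none. Bdnf, the gene of brain-derived neurotrophic factor, held a peak deeper inside the gene. This region lay at chromosome 2, 109677958 to 109678536 (mm10), 3258 bp inside the lower-coordinate end of the gene. It was called in 4 of 4 2-DG lists and in 1 of 4 control lists, control replicate 1. Ends widened to 5000 bp take in this region. The percent of 2-DG lists with a Bdnf peak then exceeded that of control lists by 75 percentage points, which restates these counts. Whether the region is exonic or intronic was not analysed here.

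Other groups showed few peaks. Activity-regulated genes reached 3 of 18 members in 2-DG replicate 1 and 0 in the other lists. Autophagy genes reached 3, 2, 2 and 0 of 16 in the 2-DG lists and 0 in the control lists (exact permutation p = 0.143, adjusted p = 0.381), and Becn1, an autophagy initiation gene, was bound in 3 of 4 2-DG lists. Glycolysis genes had 1 of 22 members bound in 2-DG replicate 1 and 0 elsewhere. N-linked glycosylation genes had 1 of 27 bound in 2-DG replicates 1 and 4. Ribosomal protein genes had 2 of 45 in 2-DG replicate 1 and 1 in 2-DG replicate 2. Neuronal markers held 2, 1, 1 and 2 of 23 in the 2-DG lists and 1 in control replicate 3 (exact permutation p = 0.0857, adjusted p = 0.274). Tubb3, the neuronal tubulin gene, was bound in 4 of 4 2-DG lists and 0 of 4 control lists. Progenitor and microglial markers had 0 members bound in all 8 lists, and astrocyte, oligodendrocyte and vascular markers had at most 1 in a list.

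Over all genes, end peaks were more frequent after 2-DG, at 774 ± 324 (SD, n = 4) genes per list against 365 ± 77.5 (SD, n = 4). The exact permutation p was 0.0286 and the adjusted p over 8 measures was 0.0762. The difference of 409 genes fell to 261 without 2-DG replicate 1 and to 175 with equal numbers of peaks per list (exact permutation p = 0.0571). The unadjusted exact permutation p was 0.0857 without any 1 control list, and 0.125 with consecutive title numbers as a block. An end peak in all 4 2-DG lists and no control list was seen for 124 genes, and 0 genes showed the reverse. The highest by within-list rank of fold were Ddit4, Rcc2, Pck2, Trib3, Taf15, Vldlr, Tmx3, Cd82, Tbl1x and Ccr10. The Ccr10 region, 1124 bp outside that gene, crosses an end of Plekhh3, which ties with Ccr10 and comes after it by name alone. Trib3 lies at chromosome 2, 152337425 to 152344060, with its peak region across a gene end at 152343372 to 152344514. The peak region of Vldlr, at chromosome 19, 27216172 to 27217249, likewise crossed a gene end, and that of Ddit4, at chromosome 10, 59952255 to 59953861, lay 485 bp outside the gene. The authors' peak fold over local background ran from 21.5 to 58.8 for Trib3 and from 66.7 to 142 for Chac1 over the 2-DG lists. Ifi202b, Fgfr1, Zfp839, 4930474N05Rik and Ilrun had an end peak in 3 of 4 control lists and 0 of 4 2-DG lists.

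End peaks were called in all 8 lists at 39 genes. The 10 highest by within-list percentile of fold, averaged over all 8 lists, were Oasl1, Lars2, Apool, Cacna2d2, Kpna1, Peg10, 4931408C20Rik, Gm40369, LOC100504180 and A530032D15Rik. At Oasl1 the authors' fold ran from 85.8 to 100 in the control lists and from 88.1 to 114 in the 2-DG lists. At Lars2, the mitochondrial leucyl-tRNA synthetase gene, it ran from 39.3 to 49.5 and from 44.0 to 55.4. Whether peaks of like fold in both treatments mark ATF4 binding was not tested, and no filter for mappability was applied here. Iars, a cytosolic synthetase gene of the list above, was also among the 39, with a fold of 22.2, 4.03, 3.74 and 4.24 in the control lists and 87.8, 79.7, 39.1 and 36.2 in the 2-DG lists. It is named after its values were seen, and folds of different lists were not tested against each other.

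**Figure D2:**
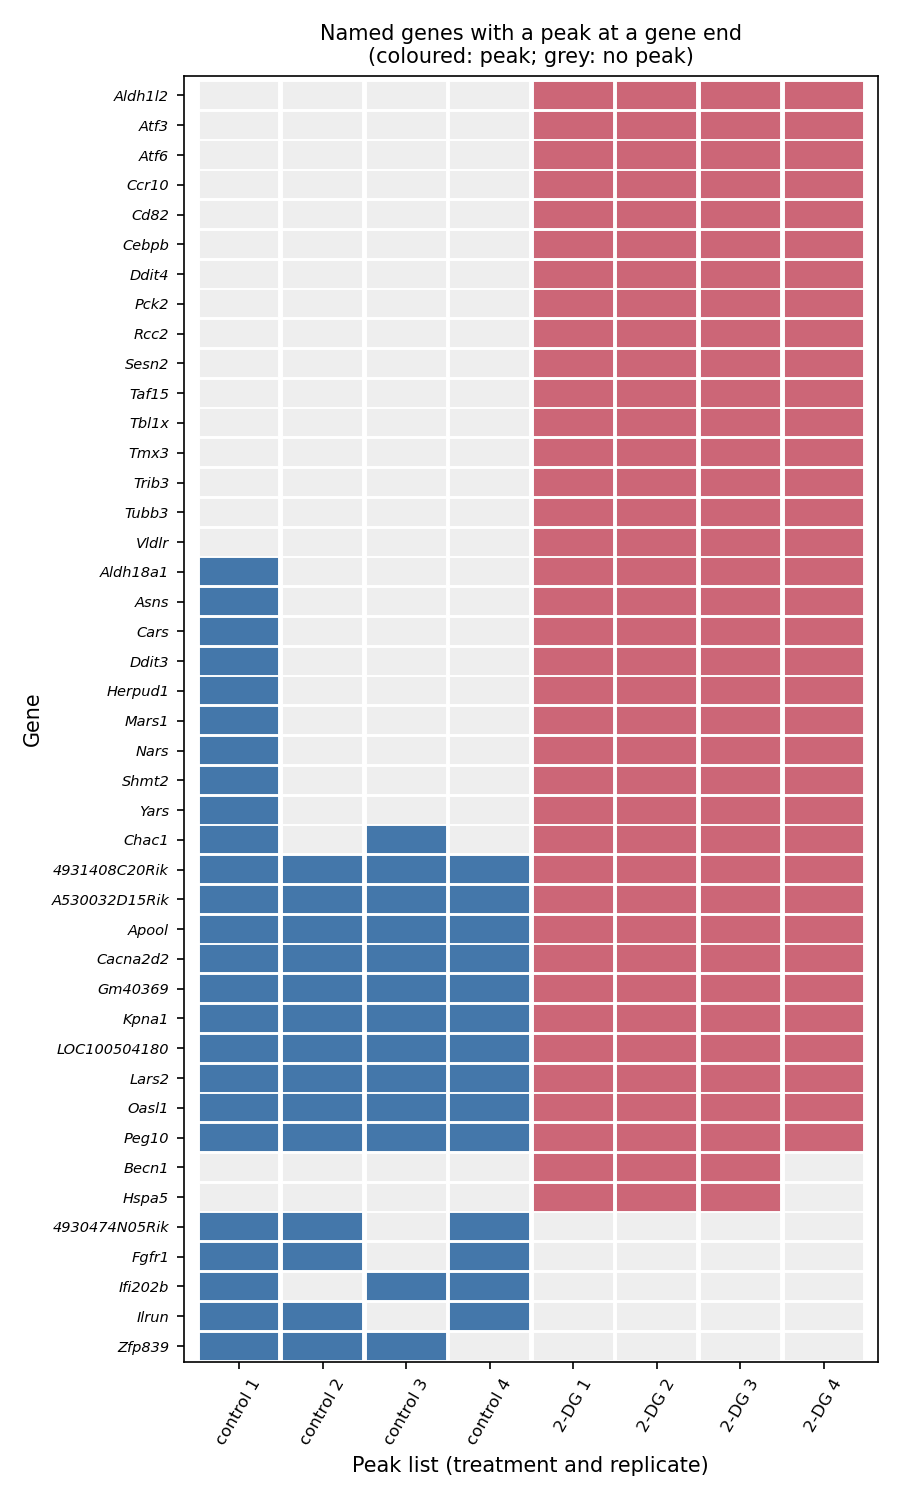
Named genes (rows) with a peak within 2000 bp of a gene end in each of the 8 peak lists (columns), coloured where a peak was called, blue for control and red for 2-DG, and grey where none was. Trib3, Ddit4 and Pck2 are coloured in 4 of 4 2-DG columns and 0 of 4 control columns, and Oasl1 and Lars2 in all 8.

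Across the genome, merging the 8 lists gave 35717 regions, of which 616 were in all 4 2-DG lists and no control list and 1 was the reverse, at chromosome 19, 52487969 to 52488246. A further 365 regions were in all 8 lists, and 26281 (73.6%) were in 1 list only. No single region could pass a test, since the lowest adjusted Fisher's exact p over regions was 1. Of the 616, 109 (17.7%) lay at gene ends, 275 elsewhere inside genes and 232 between genes. The share at gene ends was higher than the 6.39% of regions found in 1 list (Fisher's exact test, odds ratio 3.15, p = 3.82e-21, not in the plan). Regions in all 8 lists had 12.1%. The 616 regions were wider, with a median of 484 bp against 130 bp in 1 list. By the middle of each region alone, which does not depend on width, the shares were 17.2% and 6.16% (odds ratio 3.17, Fisher's exact p = 7.88e-21, chosen after the data were seen). Regions are not independent replicates in these tests. Leaving out a list eases the rule for this class. Counts of the 616 class were limited most by 2-DG replicate 3, without which 1247 regions were in the remaining 2-DG lists and no control list. Without another 2-DG list the count was 627 to 751. The class had 0 regions when the pair of lists with conflicting labels was added by description, and 524 when added by title. Of the 616, the list described as control held 527.

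**Figure D3:**
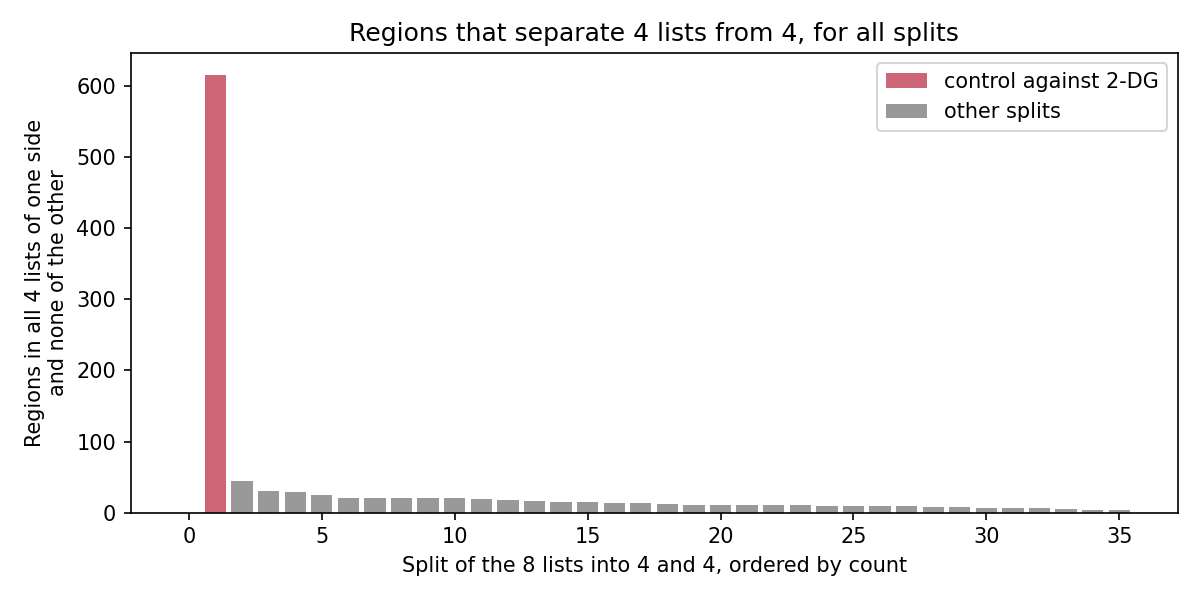
Number of regions in all 4 lists of one side and none of the other (vertical axis) for each of the 35 splits of the 8 lists into 4 and 4 (horizontal axis, ordered by count), taking the larger side of each split. The split by treatment gave 616 and the highest other split gave 45.

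Lists of 1 treatment overlapped more with each other than with lists of the other treatment. The mean Jaccard index in base pairs was 0.170 within control (6 pairs), 0.206 within 2-DG (6 pairs) and 0.138 between treatments (16 pairs). The difference, 0.0501, was the highest of the 35 splits (one-sided exact permutation p = 0.0286). It no longer passed without 2-DG replicate 1 (0.0368) or 2-DG replicate 2 (0.0355), each with an exact p of 0.0571, or with the conflicting lists added by description, or with consecutive title numbers as a block (exact p = 0.125).

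The number of peaks per list did not differ beyond the spread between lists, at 5564.5 ± 2317 (SD, n = 4) in control and 8709 ± 4399 (SD, n = 4) after 2-DG (exact permutation p = 0.257). The difference of 3144.5 peaks passed at -log10 q of at least 2, a limit above the differing ends of the lists (3686 more, exact permutation p = 0.0286). It was 1967 at -log10 q of at least 5 (exact permutation p = 0.0857) and 1461.5 at fold of at least 5 (exact permutation p = 0.114). Both filters take peaks from every list, and both p-values were lower than without a filter. The difference was 1813 with the conflicting lists added by description (exact permutation p = 0.524). Without 2-DG replicate 1 it was 967.5 (exact permutation p = 0.486). The share of summits at gene ends did not differ beyond the spread either, at 7.85% ± 2.00 in control and 9.05% ± 1.45 after 2-DG (SD, n = 4 each, exact permutation p = 0.4). Its difference turned with ends of 5000 bp. That difference of 1.20 percentage points became 3.54 with equal numbers of peaks per list (exact permutation p = 0.0571), and 0.492 without control replicate 3 and 2.03 without control replicate 1. Summits inside genes but away from their ends made up 34.3% ± 2.16 in control and 37.3% ± 0.681 after 2-DG (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.0762).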

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

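All tests in this part were chosen after the results were seen, except the comparison at equal list length and the matching over 41 megabases, whose outcomes were stated first. Of 46 groups of 4 lists screened for a list far from the others, 11 held one. A rate of 1 in 20 would give about 2.3. Most of the 11 are counts of 0 with a single list above 0, which always pass the limit. That rate does not apply to them, so no excess over chance can be read from the 11.

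2-DG replicate 1 lay far from the other 2-DG lists in number of peaks (15240) and in the percent of summits inside genes (38.3%). It was also the lone 2-DG list with activity-regulated genes bound (3), with a glycolysis gene bound (1) and with an oligodendrocyte marker bound (1). An astrocyte marker was bound in 2-DG replicate 2 alone (1). Among control lists, a neuronal marker was bound in replicate 3 alone (1), and an astrocyte, an oligodendrocyte and a vascular marker in replicate 4 alone (1 each). Control replicate 1 held 10 synthetase genes, far from the other control lists.

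The list titled 2-DG and described as control, which entered no group, held 527 of the 616 regions (85.6%, exact binomial 95% interval 82.5 to 88.2). The list titled control and described as 2-DG held 3 (0.487%, interval 0.101 to 1.42). They held 23 and 0 of the 33 ATF4 targets. By comparison, left-out 2-DG lists held 49.4% to 98.2% of regions defined without them, and left-out control lists 0.805% to 10.6%. By these shares and counts each list was nearer to the group named in its title. The values argue against the descriptions of these lists, provided that the labels of the other lists are right. No source used here states which label is right.

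The 616 regions found in all 2-DG lists and no control list were weighed first. If all 8 lists can be exchanged freely, chance is argued against but not excluded. Of 35 splits, 1, the real one, gave as many regions, the smallest share that 35 splits allow, and the highest other gave 45. For genes, 1 of 35 reached 124 and the highest other gave 3. Free exchange is itself doubtful, because the design states 3 independent replicates and nothing ties lists to separate cultures. If lists with consecutive title numbers are pairs, 8 splits part every pair, too few for a share under 0.05, and the highest other of them gave 21. Longer lists after 2-DG are argued against, because 472 regions were found with 3461 peaks from each list, when the highest other split gave 25. That the control immunoprecipitations lacked the ATF4 antibody, as their label reads, cannot be told apart from a rise in ATF4 binding, the biological explanation that the design names. Control replicate 1 did hold ATF4 targets beyond other genes (Fisher's exact p = 3.72e-11), but reads from another library stay open there.

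Control replicate 1 held 73 of the 689 regions that were in all 2-DG lists and no other control list (10.6%), against 0.805% to 2.07% for the other control lists. A candidate explanation is reads of the 2-DG replicate 1 library within it. Over the 73 regions, the rank correlation of fold was 0.423 with 2-DG replicate 1, a lead of -0.0196 over the highest with another 2-DG list (bootstrap 95% interval -0.0855 to 0.0277), so this source cannot be told apart from others. All 9 regions at synthetase genes were held, against 5.72 expected from other gene-end regions of like fold (permutation p = 0.0024, adjusted p = 0.012 over 5 gene lists). This list was picked because its genes were seen among the held regions, so the value decides nothing. ATF4 targets had 11 of 25 regions held, against 8.93 expected (permutation p = 0.158). Serine and one-carbon enzymes had 5 of 10, against 5.34 (permutation p = 0.762). Endoplasmic reticulum chaperones and neuronal markers had 1 region each, with 0 held. No biological explanation was tested, and ATF4 binding in untreated cells stays open.

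Broad peaks covered chromosome 2 from 77869686 to 78027266, over Cwc22, in some lists of both treatments, with 120 and 122 kb in control and 2-DG replicate 1, 120 and 123 kb in replicates 2, 3.88 and 3.32 kb in replicates 3, and 48.4 and 45.6 kb in replicates 4. Treatment is argued against as the source, since the largest difference within lists of consecutive title numbers was 2.58% of the range. A candidate explanation is that such lists share animals or a day of preparation, an idea that came from the 25 megabases covered for over 8 kb in some list. The matching was repeated over 41 others, covered for 4 to 8 kb at most, whose coverage per list had not been seen. There, 0.00833 of the 120 ways of matching the lists gave as high a summed correlation as the consecutive numbers. That sum was -0.0373, against a median of -1.54 over the matchings. The mean of each megabase over the lists was subtracted first, which makes correlations between lists more negative. The sign of the sum can therefore not be read as a presence or lack of correlation. Only 2 of 10 lists were most similar to the consecutive one. Copy number, mappability and a shared input were not tested and stay open.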

How the results depend on the processing

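Adding both conflicting lists by description left 0 regions in all 2-DG lists and no control list, an overlap difference of 0.0133 (exact p = 0.151) and 262 more genes with end peaks (exact p = 0.159). The ATF4 difference fell from 23 to 13.8 targets (exact permutation p = 0.0952, adjusted p = 0.508). The shares of regions held by these lists, given above, argue against that labelling. By title, the ATF4 difference stayed at 23 and passed after adjustment (exact permutation, adjusted p = 0.0423), because 5 lists against 5 allow a lower p. Also by title, 0 regions were in all control lists alone. The 616 regions became 321 at -log10 q of at least 5, 166 when a peak had to cover 50% of a region, and 1424 for at least 3 of 4 lists. The single control region became 0 at -log10 q of at least 2 or 5, at fold of at least 5 and at 50% coverage, 8 at equal list length, 2 in 500-bp windows and 41 for at least 3 of 4 lists. The difference in genes with end peaks, judged here by its unadjusted p, no longer passed at equal list length (175 more, exact p = 0.0571) or with 5000 bp (588 more, exact p = 0.114). The number of peaks passed at -log10 q of at least 2 (3686 more, exact p = 0.0286). The share of summits at gene ends reversed to -0.0681 percentage points with 5000 bp. The cause of these changes was not tested. Leaving out 1 list gave 622 to 1247 regions in 2-DG lists alone, 4 to 18 in control lists alone, an overlap difference of 0.0355 to 0.0594 and 261 to 492 more genes with end peaks. Enrichment of ATF4 targets among genes bound after 2-DG passed under every alternative run that enters it, which leaving out a control list does not. The value for a named gene was the percent of 2-DG lists with a peak at it minus that of control lists. Of 810 such values, 759 moved by at most 25 percentage points, 51 moved further and 0 reversed. The labels give no replicate number shared by the groups. Lists with consecutive title numbers were most similar to each other in 10 of 10 lists over the 25 megabases covered for over 8 kb in some list, but in 2 of 10 over 41 less covered ones. Genome-wide, 2 of 5 lists titled control had their highest Jaccard index with the consecutive list (control replicate 1 had 0.128 with 2-DG replicate 1 and 0.187 with 2-DG replicate 2), while the consecutive matching had the highest sum of 120. The pairing is a hint from the data only. With this pairing as a replicate block, chosen after the data were seen, treatments are exchanged only within 4 pairs and the smallest exact p is 0.125. No difference can pass then, and the exact test gave 0.125 for the overlap difference of 0.0501, for the 409 genes with end peaks and, before adjustment, for the 23 ATF4 targets (adjusted p = 0.5). The other alternatives chosen after the data were seen kept every call they were run on. Within consecutive title numbers, ATF4 targets were higher after 2-DG by 17, 27, 23 and 25 and genes with end peaks by 888, 537, 82 and 129, while peaks (11779, 3585, -1831 and -955) and the share of summits at gene ends (-2.75, 2.20, 2.32 and 3.02 percentage points) went both ways. The motif alternatives were not run, because no genome was used here. Depth is unknown, so it cannot be said which missing peaks lie under a limit of detection.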

Other observations

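The regions in all 2-DG lists and no control list with the highest within-list rank of fold included several away from gene ends. Most of that class lay away from gene ends, with 109 of 616 (17.7%) at them. Among the highest 13, a number chosen after the values were seen, 7 lay over 2000 bp from a gene end. Of these, 3 lay between genes, 43740 bp from Itga6, an integrin gene, 195327 bp from Gask1b and 559423 bp from Prelid2. The others lay inside Smarca2, a chromatin remodeller gene, Trim66, Ankrd45 and Tsc22d3, a glucocorticoid-induced gene, at 70470, 22492, 8601 and 5122 bp from the nearer end of that gene.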
